A study of Mus musculus with 3 samples.

How the data were processed

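Whole cochleae of C57BL/6J mice were profiled per the labels by single-cell RNA sequencing with the Chromium 3' v3 kit: 2 libraries of E15 and 1 of P7. Tissue was dissociated with papain and thermolysin and sorted against debris. The deposited counts are raw UMI counts per gene and cell barcode that the authors made by aligning and counting reads with Cell Ranger, with cells called before deposit by a rule that is not stated. The labels name Cell Ranger 6.1.2 and GRCm38; per the file headers the software version was 6.1.2 for both E15 libraries and 3.1.0 for P7. The lowest barcode total was 500 UMIs in each library. The P7 file lists 28692 genes and each E15 file 32285. The analysis used the 27734 Ensembl IDs that all 3 libraries list, which leaves out 958 genes of P7 and 4551 of E15.

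Barcodes with under 500 genes or over 20% mitochondrial UMIs were left out (595 and 284 at P7, 365 and 31 in E15 replicate 1, 350 and 10 in E15 replicate 2). Doublets were scored with the Scrublet method in scanpy. Its automatic threshold marked 3, 6 and 5 cells, so the cells with the highest scores were removed up to an expected rate of 0.008 per 1000 cells instead: 414 at P7, 60 in E15 replicate 1 and 77 in E15 replicate 2. This choice was made after the automatic result was seen. The cells used were 6848 at P7 (median 10976.5 UMIs and 3361 genes), 2778 in E15 replicate 1 (14667 UMIs and 4145.5 genes) and 3460 in E15 replicate 2 (10815 UMIs and 3521 genes).

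Cells were clustered by age in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Counts were scaled to a total of 10000 per cell and logged, genes seen in at least 5 cells were scaled with a limit of 10, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used. Clusters were named from markers of 26 cell classes fixed before the data were examined. A name needs at least 3 of a class's markers with a fold of 2 over the other cells and detection in 20% of the cluster. Mesenchymal, cartilage and bone names were given last, to clusters without another name. For these the fold was taken over the clusters that already had another name, not over all other cells. A name thus stands for cells like that type. Details of this rule were set after the clusters were seen. One was that cartilage and bone names also need 2 of their markers among the 10 leading genes. The P7 neuron cluster and the E15 macrophage cluster were seen to be mixed and were clustered again, and this too was decided after the data were seen. The 2 central glia clusters at P7, in which 51.0% and 100% of cells had at least as many UMIs of another class's markers as of their own, were not split, and their levels are not given. Clusters with no clear name (125, 120 and 283 cells in E15 replicates 1 and 2 and P7) were left out of the tests.

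UMI counts were summed per library and class. A class was tested where each library had at least 20 of its cells, which held for 7 classes. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after TMM scaling and filterByExpr, and called at a Benjamini-Hochberg adjusted p under 0.05 with a fitted fold of at least 2. The fit has 1 residual degree of freedom, so spread is pooled across genes. SE is the log2 change divided by the square root of F. Where a class had no count at 1 age, the fold is a bound against a floor of 3 counts over the group. There were 31 gene lists fixed in advance; their members were counted as called and each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation. Shares of cells carry exact 95% intervals. Cycling cells are those with at least 2 UMIs of a cell cycle list after thinning to 2000 UMIs. Figures were drawn with matplotlib 3.10.9.

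Genes are named by a rule fixed before the data were examined. In each class these are up to 8 rises and 8 falls with the largest fitted change among called genes with a level of at least 50 CPM (at P7 for a rise, in both E15 libraries for a fall) and at least 30% of the highest class in the same library, leaving out mitochondrial, ribosomal, immunoglobulin, sex-linked and unnamed genes. To these are added members of the paired lists, at most 8 called per list with the largest fold first, and cell type markers. Not all genes that the rule allows are given, and the report lists the genes that fall outside it. Some genes, 1 of them with opposite directions between classes, are not reported here.

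Calls were tested on simulated data with 200 changed genes per class. At a fold of 4 the share recovered was 96% in mesenchymal and sensory, 93% in glial, 78% in neuron, 77% in endothelial, 70% in pericyte and 66% in non-sensory sums, and 0 to 5 unchanged genes were called. At a fold of 2 the share recovered lay between 22% (pericyte) and 44% (mesenchymal). The simulation drew every library, P7 included, with the same spread fitted to these data, and changed fewer genes than were called. These rates therefore assume that P7 varies like the E15 pair, which they cannot test. Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, a test against a fold of 2, no low-count filter, joining by symbol, at most 10% mitochondrial UMIs, doublets kept, clustering of the 3 libraries together, Leiden resolution 2, thinned sums and each E15 library left out. For cycling shares, thinning to 1000 UMIs, no thinning and limits of 1 and 4 UMIs were tried. Added after the data were seen were mixed clusters kept whole, glial cells without those from the neuron cluster, clusters led by cartilage markers put back, low-UMI clusters left out, macrophages tested despite few cells, and genes left out that share exons on the same strand with a feature listed at 1 age only.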

Results

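Cells from whole mouse cochleae, the coiled hearing organs of the inner ear, were profiled by droplet-based single-cell RNA sequencing, which counts unique molecular identifiers (UMIs) per gene and cell barcode. The C57BL/6J samples fell into 2 ages: embryonic day 15 (E15, 2 libraries), when cochlear cells still divide and differentiate, and postnatal day 7 (P7, 1 library), before the onset of hearing. The P7 library held 8141 barcodes with 93829443 UMIs (median 10325 per barcode). E15 replicate 1 held 3234 barcodes with 46530036 UMIs (median 13936.5), and E15 replicate 2 held 3897 barcodes with 44304364 UMIs (median 10398). Filters left 6848, 2778 and 3460 cells in these libraries, in the same order. The comparison asks how each class of cochlear cells differed between E15 and P7. Levels are CPM, the UMIs of a gene scaled to a common total of its class. E15 levels are given with the SD of the 2 libraries, and those of the single P7 library carry no replicate error. Class names such as neuron stand for clusters that carry the markers of that cell type.

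The same classes made up the bulk of the cells at both ages, and osteoblasts, central glia and hair cells formed clusters of their own at P7. Mesenchymal cells, which build the connective tissue of the lateral wall, spiral limbus and modiolus, made up 72.9% (exact 95% interval 71.2 to 74.5) of cells in E15 replicate 1, 74.5% (73.0 to 76.0) in E15 replicate 2 and 61.3% (60.2 to 62.5) at P7. The mesenchymal share at P7 leaves out osteoblasts and a cluster of 206 cells with mesenchymal markers that a cartilage marker led. No such cluster was left out at E15. Neurons made up 4.07% (3.36 to 4.87) and 3.44% (2.86 to 4.10) at E15 and 0.336% (0.213 to 0.504) at P7, with 113, 119 and 23 cells. Endothelial cells made up 1.33% and 1.30% at E15 and 4.15% (3.69 to 4.65) at P7, macrophages 0.612% and 0.607% against 2.22% (1.88 to 2.60), and glial cells 5.51% and 5.38% against 8.22% (7.58 to 8.90). The sensory domain epithelium, which holds supporting cells and the greater epithelial ridge, made up 7.34% (6.40 to 8.38), 6.71% (5.89 to 7.59) and 6.92% (6.33 to 7.55). Osteoblasts (410 cells, 5.99%), central glia (83 cells, 1.21%) and hair cells (26 cells, 0.380%) had no E15 cluster. This does not bound the cell types at E15: 6 of 2778 cells (0.216%, 0.079 to 0.470) in E15 replicate 1 and 10 of 3460 (0.289%, 0.139 to 0.531) in E15 replicate 2 carried at least 3 hair cell markers.

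These shares were compared as values with no test, since dissociation, sorting and capture can set them and the intervals cover counting error only. Some moved by over 1.5 times with the processing: osteoblasts made up 11.5% at P7 with predicted doublets kept, neurons 1.80% at P7 and macrophages 1.73% and 1.56% at E15 with mixed clusters kept whole, and non-sensory epithelium 2.72%, 2.90% and 3.98% (0.756%, 1.42% and 1.47% as reported) with at most 10% mitochondrial UMIs per cell. Non-sensory epithelium made up 0% and 0% at E15 with the libraries clustered together and 2.92% and 3.24% at Leiden resolution 2. Pericytes made up 1.33% and 1.39% at E15 as reported, 0.734% and 0.851% with the 10% limit and 0.720% and 0.867% clustered together, and 0.810% in E15 replicate 1 with predicted doublets kept. With the 10% limit the sensory share was 4.81% in E15 replicate 1 and the melanocyte share was 0.371% at P7 (0.643% as reported). With predicted doublets kept macrophages made up 0.933% in E15 replicate 2.

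Within the 7 classes tested, the 2 E15 libraries lay closer to each other than to P7. Pearson's r of log2 levels across genes, which are not independent replicates, lay between 0.924 (non-sensory epithelium) and 0.998 (mesenchymal cells) for the E15 pair and between 0.633 and 0.855 for either of them against P7. The class counts of the E15 pair gave a chi-square of 19.4 on 14 degrees of freedom (p = 0.150). Genes were called where edgeR's quasi-likelihood test on counts summed per library and class gave an adjusted p under 0.05 and a fitted fold of at least 2. These p-values rest only on the spread between the 2 E15 libraries, pooled across genes. Pooling was full in the endothelial, neuron, non-sensory, pericyte and sensory classes. There a gene's own spread carried no weight in its p-value or SE. The labels do not describe the E15 libraries as separate litters, and the lone P7 library is assumed to vary like the E15 pair. Age cannot be told apart from the P7 library, nor from the older software version and gene annotation of its file. Among 865 calls for genes of the fixed lists and of the naming rule, the P7 level lay beyond both E15 levels in 862. The 3 exceptions were Ccnb1 and Uhrf1 in non-sensory epithelium and Pou4f3 in sensory epithelium. Called genes were selected for a fitted fold between the ages, so this count adds no support to the calls. The rule for named genes was set before the data were examined. Pmp22, Egr2, Gap43, Otor, Coch, Cldn5, Slc2a1, Apln, Crym in mesenchymal cells, Pou4f3 and Adgrv1 in sensory epithelium and the genes called in all classes fall outside it and were chosen after their values were seen.

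In glial cells, which carry markers of Schwann and satellite cells, the 20 tested genes of the myelin list all rose from E15 to P7. Pmp22, a membrane protein of peripheral myelin, rose from 158 ± 14.2 CPM (SD, n = 2) to 6639 CPM (log2 change 5.49 ± 0.13 SE, adjusted p = 6.1e-167). Cldn19, a tight junction protein of Schwann cells, had no UMI at E15 and 539 CPM at P7, at least 865-fold higher against a floor of 3 counts over the group. Pllp and Fa2h, a myelin membrane protein and a fatty acid hydroxylase, likewise had no UMI at E15 and were at least 487-fold and 194-fold higher. Pou3f1, a transcription factor that acts before myelination, rose from 7.08 ± 0.274 to 1726 CPM (8.01 ± 0.18), and Egr2, which drives myelin genes, rose by 3.75 ± 0.18 on the log2 scale.

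Myelin needs cholesterol in bulk. Of the 20 genes of cholesterol synthesis, 16 rose in glial cells and 4 were not called. Msmo1, an enzyme of the pathway, rose by 2.87 ± 0.15 and Insig1, a sensor that restrains it, by 2.81 ± 0.23, while Srebf2, its main transcription factor, had a log2 change of 0.95 ± 0.18. Of 15 genes of the glial progenitor and early Schwann lineage, 4 rose and 4 fell: Fabp7, a lipid carrier of glial progenitors, fell from 5805 ± 309.7 to 1268 CPM (-2.11 ± 0.14) and Ngfr, the neurotrophin receptor of immature Schwann cells, fell from 124 ± 22.0 to 17.2 CPM (-2.76 ± 0.19). Sox10, which sets glial identity, was at 475 ± 35.1 and 412 CPM (log2 change -0.12 ± 0.13, not called). Vcan, a matrix proteoglycan, fell from 297 ± 36.2 to 1.20 CPM (-7.82 ± 0.29), and Igf2bp1, an RNA-binding protein of fetal tissue, went from 69.6 ± 3.18 CPM to no UMI, at least 97.1-fold lower.

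Over the 11322 genes tested in glial cells, 1907 were called higher and 1668 lower at P7; DESeq2 called 2204 in all, and the test against a fold of 2 called 2260. The counts of 20, 16, 4 and 4 list genes were the same adjusted over the list alone, and 4 myelin genes were also markers that named the class. Camera, which compares a list with all other genes, called 100 of the 197 lists tested over the classes with a preset correlation and 0 with an estimated correlation. The second test rests on 1 residual degree of freedom and can call little, so the 0 reflects the design as well, and no list is claimed to change beyond other genes. For myelin this gave adjusted p = 0.445 with an estimated correlation, for cholesterol synthesis adjusted p = 0.475 and for the progenitor list adjusted p = 0.495. At P7 17 of the myelin genes and 6 of the cholesterol genes stood at 30% or more of the highest class, so free RNA can add to the others. Lists of other cell types rose here too: 14 of 16 fibrocyte genes (1 at 30% or more of the highest class), 10 of 16 collagens (4), 10 of 11 cartilage and bone genes (1) and 7 of 8 macrophage genes (0), with adjusted p = 0.445, 0.475, 0.445 and 0.445 with an estimated correlation.

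In neurons, genes of mature firing and transmitter release rose and genes of neuronal differentiation and axon growth fell. Of 26 excitability and release genes, 20 rose, 0 fell and 6 were not called. Nefh, the heavy neurofilament of large axons, rose from 32.4 ± 0.0849 to 1849 CPM (5.97 ± 0.17, adjusted p = 7.8e-259). Scn1a, a sodium channel, rose from 4.21 ± 0.351 to 198 CPM (5.67 ± 0.29), Kcna2, a potassium channel, by 5.24 ± 0.28 and Slc17a7, a vesicular glutamate transporter, by 5.13 ± 0.25. Of 18 differentiation genes, 12 fell and 0 rose. Neurod1, a transcription factor of neuroblasts, fell from 305 ± 62.3 to 12.6 CPM (-4.44 ± 0.30), and so did Dcx, a microtubule protein of migrating neurons (-3.75 ± 0.26), and Gap43, a growth cone protein (-2.60 ± 0.18). Insm1 went from 67.0 ± 0.332 CPM to no UMI, at least 17.7-fold lower. Tubb3, a neuronal tubulin, was at 2068 ± 202.9 and 1208 CPM (-0.63 ± 0.15, not called).

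Among 14 markers of spiral ganglion neuron subtypes, 5 rose and 5 fell. Calb2, the calcium buffer calretinin, was at 0.955 ± 1.35 CPM (3 UMIs) at E15 and 3246 CPM at P7, and Th, the enzyme of catecholamine synthesis, rose by 4.21 ± 0.61 from 6 UMIs. Calb1, another calcium buffer, fell from 184 ± 42.2 to 54.4 CPM (-1.62 ± 0.23) and Gata3, a transcription factor of auditory neurons, from 464 ± 36.8 to 121 CPM (-1.79 ± 0.18). Thy1, a surface glycoprotein of mature neurons, had no UMI at E15 and 229 CPM at P7, at least 235.5-fold higher. Lypd1 rose by 1.93 ± 0.14, but its change was 0.71, not called, with the mixed P7 cluster kept whole.

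Neurons at P7 were 23 cells, sorted out of a cluster that was mostly glial after it had been seen to be mixed. Their Pmp22 level was 1374 CPM, 20.7% of that in glial cells. The 15 myelin genes tested in neurons all rose, with 2 at 30% or more of the highest class. Otos and Car3 of fibrocytes and Bglap and Ibsp of osteoblasts were also called higher, as in all 7 classes. Free RNA can therefore add to rises in neurons. Of 10464 genes, 1725 were called higher and 1651 lower; DESeq2 called 1569, the test against a fold of 2 called 1853, and with the cluster kept whole 2351 were higher and 1817 lower. List counts were the same adjusted over the list alone. The adjusted p with an estimated correlation was 0.493 for excitability, 0.493 for differentiation and 0.553 for subtypes.

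In mesenchymal cells, the 19 tested genes of the fibrocyte list all rose. Otos (otospiralin, a secreted protein of cochlear fibrocytes) had 1 UMI over both E15 libraries and 536475 UMIs, or 10410 CPM, at P7. Car3, a carbonic anhydrase, rose from 49.7 ± 14.2 to 3069 CPM (6.03 ± 0.12), Emilin2, a matrix glycoprotein, from 10.6 ± 0.347 to 1289 CPM (7.01 ± 0.11), and Otor (otoraplin) from 931 ± 65.2 to 9630 CPM (3.45 ± 0.08, adjusted p = 8.2e-40). Gjb2, a gap junction protein whose loss causes deafness, rose from 1.24 ± 0.629 to 219.9 CPM (7.55 ± 0.14). Of 16 collagens, 6 rose and 2 fell: Col15a1 rose by 6.46 ± 0.11, Col9a1 by 4.32 ± 0.09 and Col2a1 by 2.90 ± 0.08, while Col6a3 changed by -2.34 ± 0.11 and Col5a1 by -1.22 ± 0.11. Of 15 transcription factors of otic mesenchyme, Tbx1 rose by 1.18 ± 0.08, Twist2 and Foxp2 fell (-1.27 ± 0.09 and -1.17 ± 0.11) and 12 were not called, among them Pou3f4 (439 ± 20.4 and 379.6 CPM).

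Outside the lists, Ecrg4, a secreted peptide precursor, rose from 2.06 ± 0.841 to 2187 CPM (10.14 ± 0.15) and Rarres1 from 0.110 ± 0.113 to 572 CPM (12.40 ± 0.19). Crabp1, a retinoic acid carrier, fell from 85.9 ± 4.43 to 0.233 CPM (-8.42 ± 0.18), and Pclaf, a replication factor, from 328 ± 12.6 to 1.88 CPM (-7.36 ± 0.16). Over 15332 genes, 3648 were called higher and 2371 lower. The list counts were the same adjusted over the list alone, and 4 fibrocyte genes were also markers of the class. The adjusted p with an estimated correlation was 0.441 for the fibrocyte list, 0.525 for collagens and 0.839 for transcription factors. At P7 10 fibrocyte genes stood at 30% or more of the highest class, and Gjb6, Ptgds and Coch were among the 9 that did not.

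**Figure D1:**
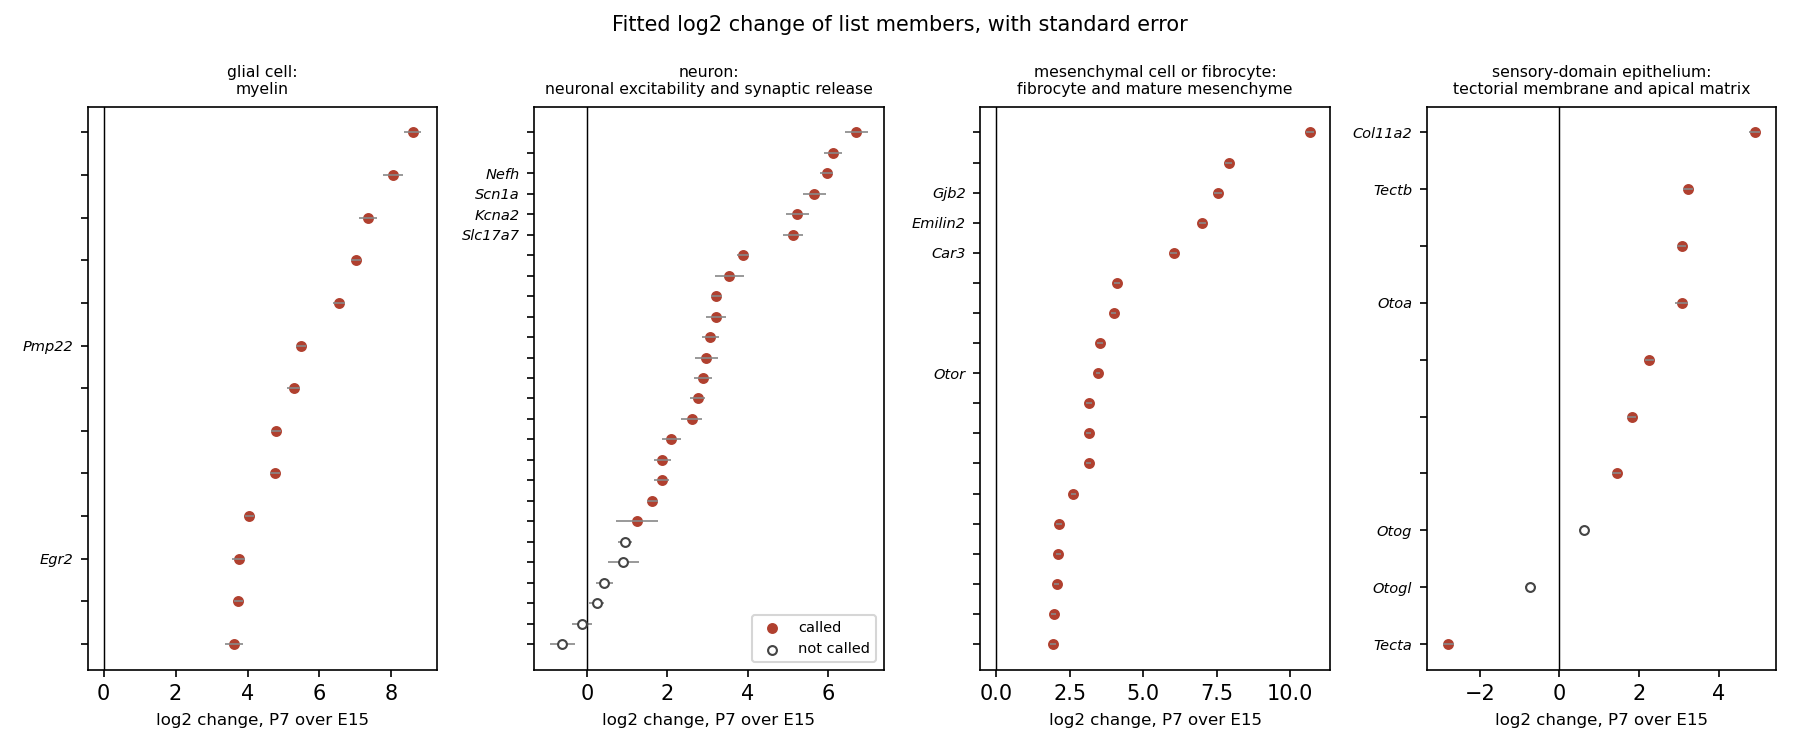
Log2 change from E15 to P7 of each member of 4 lists (myelin in glial cells, excitability and release in neurons, fibrocyte genes in mesenchymal cells, tectorial membrane in sensory epithelium), with bars for the SE of the fit. Genes with 3 or fewer counts at either age are left out, and names are given for genes with values in the text; Pmp22 sits at 5.49, Nefh at 5.97, Otor at 3.45 and Tecta at -2.79.

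In the sensory domain epithelium, most genes of the tectorial membrane list rose while Tecta fell. The tectorial membrane is the sheet that couples hair bundles to sound. Of 12 tested, 9 rose and 1 fell. Tectb (beta-tectorin) rose from 667.5 ± 103.2 to 5387 CPM (3.22 ± 0.12, adjusted p = 4.0e-153), Col11a2 from 22.1 ± 4.41 to 561 CPM (4.90 ± 0.14) and Otoa (otoancorin, which attaches the membrane) from 17.4 ± 8.37 to 122 CPM (3.07 ± 0.17). Umodl1 had no UMI at E15 and 18.5 CPM at P7. Tecta (alpha-tectorin) fell from 366 ± 17.5 to 45.5 CPM (-2.79 ± 0.14), and Otog (0.62 ± 0.14) and Otogl (-0.73 ± 0.15) were not called. The list also holds collagens that other classes carry: in mesenchymal cells at P7 Col2a1 stood at 5890 CPM and Col9a1 at 4129 CPM. Col11a2 was called higher in all 7 classes, and its rise is not specific to this class. Of 19 fibrocyte genes tested in sensory epithelium, 18 rose, with 5 at 30% or more of the highest class (adjusted p = 0.583 with an estimated correlation), so free RNA or shared genes can add to the rises.

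Of 14 Notch pathway genes, 3 rose and 4 fell in this class: Heyl, a target of the pathway, rose by 4.79 ± 0.34 and Lfng, which tunes Notch receptors, by 2.67 ± 0.17. Hes6 changed by -1.33 ± 0.15 and Jag2, a ligand, by -3.91 ± 0.55. Hes1 rose by 1.46 ± 0.15 (0.84, not called, with at most 10% mitochondrial UMIs). Of 4 gap junction genes, Gjb6 (4.41 ± 0.19) and Gjb2 (1.54 ± 0.11) rose and Gjc1 (-2.30 ± 0.20) and Gja1 (-3.22 ± 0.36) fell. Of 5 cell cycle inhibitors, 3 rose, among them Cdkn1a (2.66 ± 0.12) and Btg2 (2.10 ± 0.12), Cdkn1c fell (-2.16 ± 0.13), and Cdkn1b was at 330 ± 6.44 and 301 CPM (0.08 ± 0.12). Scg2, a granin of secretory vesicles, and Tmprss9, a serine protease, had no UMI at E15 and 503 and 859 CPM at P7, at least 818-fold and 1397-fold higher. Tac1, the precursor of substance P, went from 257 ± 10.9 CPM to no UMI, at least 547-fold lower, and Fgf20, a growth factor of the sensory domain, fell from 82.0 ± 0.0707 to 0.939 CPM (-6.19 ± 0.31).

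Of 12021 genes tested in sensory epithelium, 2311 were called higher and 1957 lower; DESeq2 called 2696 and the test against a fold of 2 called 2748. List counts were the same adjusted over the list alone, and 4 tectorial and 3 Notch genes were markers of the class. The adjusted p with an estimated correlation was 0.591 for the tectorial list, 0.979 for Notch, 0.762 for gap junctions and 0.630 for inhibitors. Heyl, Hes1, Jag2, Gjb6, Gja1 and Cdkn2d stood below 30% of the highest class. Cells with at least 3 hair cell markers stayed in this class at both ages, and a hair cell cluster was found at P7 alone. At P7 the sensory class held 1 UMI of Gfi1 and 0 of Otof and Atoh1. The other markers there included Smpx (409 UMIs), Acbd7 (282) and Cib2 (273). How far the separate P7 cluster moves hair cell genes in the sensory class was not tested. Pou4f3 had 81 UMIs in E15 replicate 1, 0 in E15 replicate 2 and 1 at P7, and Adgrv1 changed by -3.93 ± 0.50.

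Hair cells at P7 carried genes of both transduction and transmitter release. Their median mitochondrial share was 12.97%, above the 10% limit tried as an alternative, under which their levels are not given. Ocm, a calcium buffer of outer hair cells, stood at 11890 CPM (exact Poisson 95% interval 11660 to 12120). Pou4f3, a hair cell transcription factor, stood at 901 CPM (838 to 967) against 0.157 CPM in the P7 sensory epithelium. Tmc1, part of the transduction channel, stood at 303 CPM (267 to 343), Otof, which triggers release at the ribbon synapse, at 636.5 CPM (584 to 693) and Slc26a5, the motor protein prestin, at 270.1 CPM (236 to 308). Tmc2, the channel's early form, was at 4.76 CPM (1.30 to 12.2) and Atoh1, which starts hair cell formation, at 3.57 CPM (0.736 to 10.4). The hair cell markers, Pou4f3, Otof and Atoh1 among them, were used to name this cluster. Their levels and counts in it therefore add no support to its name. At least 3 hair cell markers were found in 25 of 26 hair cells (96.2%, median 34329.5 UMIs) and in 33 of 474 P7 sensory cells (6.96%, median 9621.5). They were also found in 12 of 4200 P7 mesenchymal cells, which should lack them (0.286%, median 11628.5). At E15 they were found in 6 of 204 sensory cells (2.94%, 1.09 to 6.29) and 5 of 232 (2.16%, 0.703 to 4.96), against 0 of 2024 and 2 of 2578 mesenchymal cells, with median UMIs of 12302.5, 8264, 15102 and 11197. No test between ages was made, since no E15 cluster was named hair cell.

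In non-sensory epithelium (roof, outer sulcus and Reissner's membrane), genes of ion transport rose. Of 11 tested, 9 rose and 1 fell: Atp1b1, a subunit of the sodium pump, rose from 79.0 ± 25.1 to 877 CPM (3.51 ± 0.24, adjusted p = 3.4e-47), and Slc12a2, a sodium, potassium and chloride cotransporter, rose by 3.03 ± 0.28. Kcnq1, a potassium channel, had no UMI at E15 and was at least 12.5-fold higher. Slc26a4, the anion exchanger pendrin, was at 2.40 ± 0.214 CPM (3 UMIs) and 159 CPM. Esrrb, a nuclear receptor, fell (-2.87 ± 0.95; -1.16, not called, with at most 10% mitochondrial UMIs, nor called by DESeq2). Crhbp, which binds corticotropin-releasing hormone, was at 1.13 ± 1.59 CPM (2 UMIs) and 5737 CPM, and Anxa1, an annexin, rose from 3.68 ± 2.02 to 3074 CPM (10.00 ± 0.39). H19, an imprinted RNA, fell from 247 ± 4.24 to 5.84 CPM (-5.25 ± 0.35). Gjc1, the tested gap junction gene, fell (-3.37 ± 0.45), with a log2 change of -2.52 without E15 replicate 2.

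Over 9787 genes, 1688 were called higher and 1304 lower; DESeq2 called 937 and the test against a fold of 2 called 1528. The class held 21 cells in E15 replicate 1, and with sums thinned to the smallest library edgeR called 0 genes, with 2345 at an unadjusted p under 0.05 and 518 called by DESeq2. Counts of the ion transport list were the same adjusted over the list alone (adjusted p = 0.721 with an estimated correlation), and 7 of its 9 rises stood at 30% or more of the highest class. Atp1b1 was called higher in all 7 classes. Lists of other cell types rose here too: 14 of 15 fibrocyte genes (5 at 30% or more of the highest class), 7 of 8 myelin genes (2) and 6 of 6 macrophage genes (0), with adjusted p = 0.721, 0.756 and 0.721 with an estimated correlation, so free RNA can add to rises in this class.

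In endothelial cells, genes of the vascular barrier rose. Of 20 tested, 13 rose, 1 fell and 6 were not called (14 and 1 adjusted over the list alone). Cldn5, the main tight junction protein of vessels, rose from 983.5 ± 214 to 3021 CPM (1.69 ± 0.13, adjusted p = 1.6e-33), Ocln, another, by 4.55 ± 0.45 and Mfsd2a, a lipid carrier that limits transcytosis, by 4.91 ± 0.39. Abcb1a, a drug efflux pump, rose by 3.88 ± 0.24 and Slc2a1, the glucose transporter of barrier vessels, from 249.8 ± 46.0 to 1040 CPM (2.12 ± 0.17). Slco1a4, an organic anion transporter, had no UMI at E15 and 572 CPM at P7, at least 234-fold higher. Plvap, a protein of leaky vessels, was at 785 ± 112 and 436 CPM (-0.78 ± 0.17, not called), and Apln, a ligand of sprouting tips, fell (-1.11 ± 0.26, not called by DESeq2 or against a fold of 2). Mest, an imprinted gene, fell from 1928 ± 72.8 to 9.73 CPM (-7.55 ± 0.24, adjusted p = 3.6e-198). Over 8081 genes, 1072 were called higher and 814 lower; DESeq2 called 727 and the test against a fold of 2 called 822. The barrier list gave adjusted p = 0.388 with an estimated correlation, and 11 of its 13 rises stood at 30% or more of the highest class at P7. Lists of other cell types rose here too: 11 of 12 fibrocyte genes (0 at 30% or more of the highest class), 6 of 8 myelin genes (0) and 3 of 5 macrophage genes (1), with adjusted p = 0.445, 0.556 and 0.445 with an estimated correlation, so free RNA can add to rises in this class.

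In pericytes and smooth muscle cells, Col4a4 and Col4a3, chains of basement membrane collagen, had no UMI at E15 and 176 and 145 CPM at P7, at least 94.7-fold and 78.0-fold higher. Col4a3 was also called higher in mesenchymal cells (2 UMIs at E15 and 55.8 CPM at P7). Spon2, a matrix protein, rose from 3.08 ± 0.596 to 274 CPM (6.42 ± 0.34). Of 10 barrier genes tested here, 2 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.973 with an estimated correlation): Angpt2, a vessel-destabilising ligand of mural cells, rose by 2.78 ± 0.37 and Itm2a fell (-2.29 ± 0.26). Over 9296 genes, 1352 were called higher and 1043 lower; DESeq2 called 792 and the test against a fold of 2 called 1118. With at most 10% mitochondrial UMIs 315 genes were called, Angpt2 and Itm2a not among them, and 0 barrier genes were lower. With the libraries clustered together 2 barrier genes were lower. Lef1, which fell (-1.60 ± 0.38), changed by 2.50 with predicted doublets kept. Lists of other cell types rose here too: 6 of 7 myelin genes (0 at 30% or more of the highest class), 9 of 13 fibrocyte genes (1), 8 of 10 cartilage and bone genes (0) and 5 of 8 macrophage genes (0), each with adjusted p = 0.510 with an estimated correlation, so free RNA can add to rises in this class.

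Cells of most classes cycled at E15, and far fewer did at P7. After every cell was thinned to 2000 UMIs, at least 2 UMIs of the cell cycle list were found in 76.6% (68.8 to 83.2) and 80.7% (74.1 to 86.2) of glial cells at E15 and 11.2% (8.61 to 14.2) at P7, and in 52.7%, 52.1% and 6.01% (5.29 to 6.79) of mesenchymal cells. Shares in endothelial cells were 77.1%, 62.2% and 19.1% (14.5 to 24.4), in pericytes 62.2%, 60.4% and 20.8% (15.0 to 27.8), and in sensory epithelium 33.7%, 34.6% and 3.73% (2.15 to 5.99). Neurons, which have left the cell cycle, gave 11.3% (5.80 to 19.4) and 6.93% (2.83 to 13.8) at E15 and 5.26% (0.133 to 26.0) of 19 cells at P7. Shares in non-sensory epithelium were 28.6%, 42.9% and 6.19% (2.30 to 12.98). The P7 shares of glial, mesenchymal, non-sensory and sensory cells do not stand above the highest neuron share. In the gene tests, all 26 cell cycle genes fell in endothelial, glial, mesenchymal and pericyte cells, 25 of 25 in non-sensory, 24 of 26 in sensory and 3 of 7 in neurons, the same adjusted over the list alone; adjusted p with an estimated correlation lay between 0.388 and 0.756. Mki67, a mark of dividing cells, fell from 154 ± 15.3 to 1.55 CPM in mesenchymal cells (-6.54 ± 0.16).

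The cycling shares carry no test between ages. The E15 mean minus P7 moved by over 1.5 times in endothelial cells (50.6 points, 27.8 without thinning and 30.2 at 1 UMI), non-sensory (29.5 points, 17.0 thinned to 1000 UMIs, 16.2 without thinning and 17.9 at 4 UMIs) and sensory epithelium (30.4 points, 18.98 thinned to 1000 and 15.3 at 4 UMIs) and neurons (3.87 points, 13.03 at 1 UMI, 0.754 without thinning and 0.495 at 4 UMIs). With at most 10% mitochondrial UMIs, 7 cell cycle genes were called lower in pericytes, while the median log2 change of the list was -2.77 against -2.43 as reported. Under that limit the spread was pooled less across genes (2.22 prior degrees of freedom), which was not tested apart. The list's median moved most in non-sensory epithelium, from -4.88 to -2.56 without E15 replicate 2, and in glial cells, from -4.14 to -1.96 with the libraries clustered together.

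**Figure D2:**
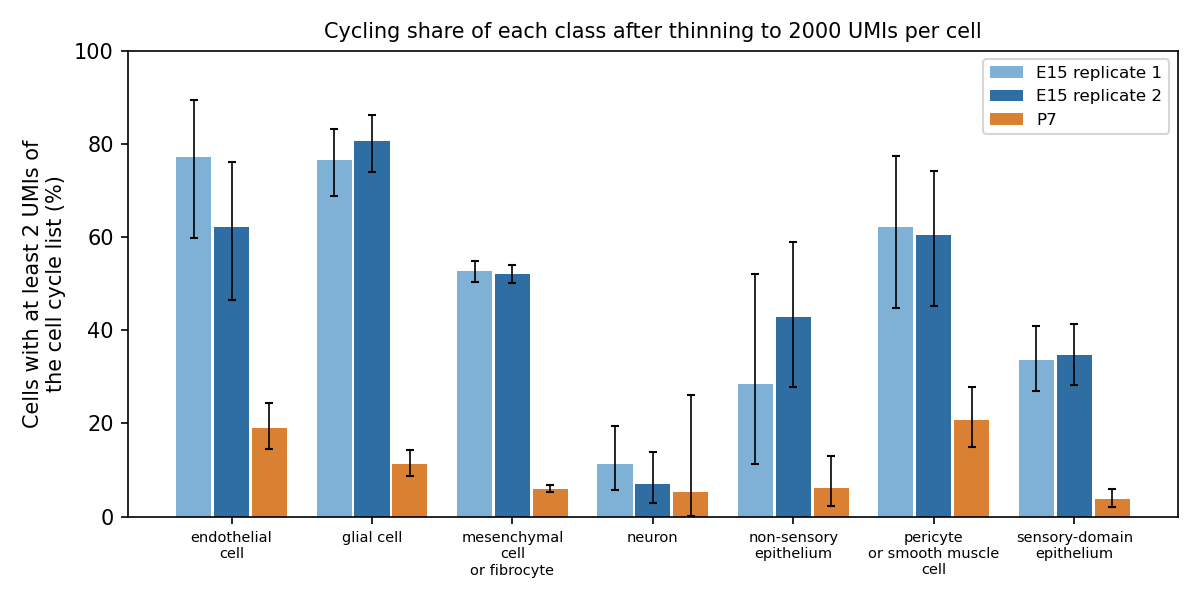
Share of cells (percent) with at least 2 UMIs of the cell cycle list after thinning to 2000 UMIs, per class and library, with exact 95% intervals as bars. In glial cells the E15 libraries sit at 76.6% and 80.7% and P7 at 11.2%, and in neurons all 3 libraries sit at or below 11.3%.

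Fetal growth and imprinted genes fell in most classes: 10 of 15 tested in endothelial, 9 of 18 in glial, 13 of 21 in mesenchymal, 8 of 15 in neurons, 9 of 15 in non-sensory, 15 of 18 in pericytes and 12 of 17 in sensory epithelium, while 3 rose in glial cells, 4 in neurons and 1 in sensory epithelium. Adjusted over the list alone, 5 rose in neurons and 10 fell in non-sensory epithelium, with the other counts the same. Igf2, the fetal growth factor, fell from 567 ± 71.4 to 14.4 CPM in endothelial cells (-5.22 ± 0.26) and was at 248 ± 11.7 and 416 CPM in mesenchymal cells (0.83 ± 0.10, not called). The adjusted p with an estimated correlation lay between 0.388 and 0.739, and 5 genes of the list were called lower in pericytes with at most 10% mitochondrial UMIs.

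Hormone target genes moved in all 7 classes. Klf9, which thyroid hormone and glucocorticoids induce, rose in each, from 5.05 ± 0.453 to 497 CPM in mesenchymal cells (6.70 ± 0.12) and by 4.14 ± 0.17 in glial cells, while Fkbp5, a glucocorticoid target, fell in each, from 30.7 ± 0.785 to 2.56 CPM in mesenchymal cells (-3.50 ± 0.12) and with a log2 change of -1.55 ± 0.22 in sensory epithelium. DESeq2 called neither gene in neurons nor Fkbp5 in non-sensory epithelium. With at most 10% mitochondrial UMIs Fkbp5 was not called in pericytes or non-sensory epithelium. Klf9 was not among the genes, given below, that rose in all classes with no overlap found and a high level in every class. Free RNA or the difference in gene annotation can therefore add to the rise of Klf9 in some classes. Of the list, 6 of 8 tested genes rose and 1 fell in endothelial, 7 of 12 and 1 in glial, 11 of 13 and 1 in mesenchymal, 4 of 10 and 3 in neurons, 8 of 12 and 2 in non-sensory, 7 of 10 and 1 in pericytes (2 rose with the 10% limit) and 7 of 11 and 1 in sensory cells, the same adjusted over the list alone. The adjusted p with an estimated correlation lay between 0.441 and 0.739.

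Immediate early and heat shock genes, which dissociation can induce, mostly rose in 6 of the 7 classes: 13 of 14 tested in endothelial, 14 of 16 in glial, 16 of 16 in mesenchymal, non-sensory and sensory, 13 of 16 in pericytes (2 rose with the 10% limit). In neurons 4 of 11 rose, 2 fell and 5 were not called. Fos rose from 431 ± 6.72 to 3891 CPM in mesenchymal cells (3.26 ± 0.08) and was at 174 ± 1.70 and 308 CPM in neurons (0.97 ± 0.16, not called). Of 14 interferon response genes, 8 of 10 tested rose in endothelial and glial cells, 8 of 14 in mesenchymal, where 1 fell, 9 of 10 in non-sensory (10 adjusted over the list alone), 5 of 8 in pericytes (2 rose with the 10% limit) and 6 of 7 in sensory epithelium, and 1 of 2 fell in neurons; at P7 0 of the mesenchymal and sensory rises stood at 30% or more of the highest class. Other counts were the same adjusted over the list alone, and the adjusted p with an estimated correlation was 0.388 or above for the immediate early list and 0.445 or above for interferon.

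Of the genes whose mutations cause hereditary deafness, 32 of 67 tested rose and 4 fell in mesenchymal cells, 23 of 60 and 13 in sensory epithelium (14 fell adjusted over the list alone), 15 of 45 and 6 in non-sensory epithelium (16 rose adjusted over the list alone), 13 of 36 and 3 in glial cells, 12 of 38 and 8 in neurons, 6 of 28 and 1 in pericytes (3 rose with the 10% limit) and 4 of 17 and 0 in endothelial cells. Crym, a thyroid hormone binding protein, fell from 2326 to 156 CPM in mesenchymal cells (-3.82), and Col11a2 rose from 10.3 to 936.5 CPM (6.59). With at most 10% mitochondrial UMIs, 23 of the deafness genes were called higher in non-sensory epithelium, 14 in glial cells and 25 in mesenchymal cells. Clustered together, 28 were higher in mesenchymal cells and 11 in glial cells. A call does not need a high level: Esrrb, called higher in mesenchymal cells, stood at 1.98 CPM there at P7. Free RNA can add to such rises. Of 30 genes of oxidative phosphorylation, 21 rose in neurons, 6 in sensory and 3 in non-sensory epithelium, Ndufa4 fell in pericytes (-1.67, not called with the 10% limit), and 0 were called in endothelial, glial and mesenchymal cells by edgeR. The adjusted p with an estimated correlation was 0.441 or above for the deafness list and 0.445 or above for oxidative phosphorylation.

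Across the 6634 genes tested in all 7 classes, 87 were called higher in all and 125 lower in all, 303 were called higher in at least 1 class and lower in at least 1, and 2768 in none. Of the 87, 14 had no overlap found with a feature of a single age and stood over 30% of the highest class in every class. Among them were Nr1d2, a repressor of the circadian clock (median log2 change 1.95), Nfic (2.33) and the mitochondrial genes mt-Co1 (2.32) and mt-Co3 (2.10). The median mitochondrial share of the cells used was 4.34% at P7 and 1.66% and 1.46% at E15, and the rise of these 2 genes was not tested apart from this difference. The 87 also hold markers of fibrocytes and osteoblasts: at P7 Otos stood at most at 2.11% of its highest class level outside mesenchymal cells and Bglap at most at 1.31% in the 7 classes, so free RNA can add to such calls. Of the 87 and the 125, 9 and 19 share exons on the same strand with a feature that the file of a single age lists. For 78 and 106 no such overlap was found, though not every feature of a single age could be searched. Calls for Rnasek, Mrpl53, Prnd, Galnt2 and Gpc2, which share exons in this way, are uncertain for that reason. Srp54c was called higher and its paralog Srp54a lower in all 7 classes, and both calls are uncertain.

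Examples of the named genes in the reference annotation (GRCm38) are Cldn19 (ENSMUSG00000066058, chromosome 4, 119255414 to 119262438, plus strand), Otos (ENSMUSG00000044055, chromosome 1, 92644218 to 92648841, minus strand) and Calb2 (ENSMUSG00000003657, chromosome 8, 110137502 to 110168210, minus strand), Tac1 (ENSMUSG00000061762, chromosome 6, 7554879 to 7565834, plus strand), Crhbp (ENSMUSG00000021680, chromosome 13, 95431371 to 95444924, minus strand), Slco1a4 (ENSMUSG00000030237, chromosome 6, 141805440 to 141856199, minus strand) and Col4a4 (ENSMUSG00000067158, chromosome 1, 82448423 to 82586849, minus strand), all annotated as protein-coding genes.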

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

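The tests of a dissociation response and of free RNA outside neurons, both for immediate early genes, and of E15 levels for fewer cycling cells were chosen only after the result was seen. In the genes that the file of a single age lists, and that no comparison uses, lay 0.143% of UMIs at P7, 0.670% in E15 replicate 1 and 0.643% in E15 replicate 2, above the limit that a count of 0 allows.

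Some genes moved in opposite directions between classes; these differences between classes were not tested. Cdkn1c, an imprinted cell cycle inhibitor, rose in glial cells (4.29) and fell in neurons (-4.84), non-sensory (-3.34) and sensory epithelium (-2.16). Mycn rose in glial cells (2.01) and fell in neurons (-4.61) and sensory epithelium (-2.04). Mest rose in neurons (1.66) and fell in endothelial (-7.55), glial (-4.44) and pericyte cells (-5.62), and Peg3 rose in neurons (2.47) and fell in glial (-1.67), mesenchymal (-2.02) and non-sensory cells (-3.09). Crym fell in mesenchymal cells (-3.82) and rose in neurons (1.89), and Esrrb rose in mesenchymal cells (5.40) and fell in non-sensory epithelium (-2.87). In mesenchymal cells Esrrb was at 0.0916 and 0 CPM in the E15 libraries and 1.98 CPM at P7, so free RNA can add to this rise. In non-sensory epithelium Esrrb was at 22.96 and 14.62 CPM at E15 and 2.12 CPM at P7. That fall was not called by DESeq2 or under the stricter mitochondrial limit. Gsdme rose in glial cells (3.48) and neurons (1.53) and fell in non-sensory epithelium (-1.88), and Tsc22d3 rose in endothelial cells (2.52), neurons (1.94) and pericytes (1.55) and fell in non-sensory epithelium (-1.16). Ndufa4 rose in neurons (1.72) and fell in pericytes (-1.67). In neurons, Mest ended at 0.24 and Crym changed sign to -0.58 with predicted doublets kept, and Tsc22d3 was not called (0.92) with the mixed cluster kept whole.

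Genes called the same way in all 7 classes were weighed against causes other than age. Among the 87 higher genes 10.3% share exons on the same strand with a feature listed at 1 age only, against 2.08% of the other 6547 genes (Fisher's exact p = 0.000107), and among the 125 lower genes 15.2% against 1.94% (p = 1.64e-11). Reads divided differently by the 2 annotations may therefore account for part of both groups, while no such overlap was found for 78 and 106 of the genes. The reference annotation searched holds 682 of the 958 features listed at P7 only and 4501 of the 4551 listed at E15 only. Overlaps with the rest could not be seen, so these 78 and 106 genes are not shown to be free of this cause. Free RNA from an abundant class was tested by the lowest class level as a share of the highest: its median over the higher genes was 15.0%, between the limits of 5% and 30% set in advance, with 28 genes under 5% and 18 over 30%, so it cannot be told apart from a rise in every class. For fewer cycling cells at P7, the test set in advance compared falls without the cell cycle list and histones: the median of 110 genes was -2.75 in neurons and -2.55 in the other classes, a difference of -0.193. It decides nothing, since these genes were chosen for a fall in every class, neurons included. It was replaced by their E15 levels: genes of cycling cells would be low in neurons, as were the 3 cell cycle genes called lower in all classes, at a median of 0.154 of the median of the other classes. The 110 genes stood at 0.855 (quartiles 0.537 and 1.20), which argues against fewer cycling cells as the cause for most of them, although a call in neurons favours genes with a higher level there. Age, library and software version differ together, so age stays open and was not tested apart from them.

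Most immediate early genes were called higher in 6 of the 7 tested classes, while in neurons 4 of 11 were higher and 2 lower. A response to dissociation at P7 would raise the list and the heat shock genes in each class. The lowest median of the list was 0.62, in neurons, and the mean of the heat shock genes tested was below 1 in endothelial cells (0.79) and neurons (0.62, from Dnajb1 alone) and between 2.12 and 4.48 elsewhere, so a dissociation response cannot be told apart from a difference with age. For free RNA, the lowest class level was a median of 3.38% of the highest, under the limit of 5% set in advance, and this came from neurons (3.61%). For the other 6 classes a first test compared CPM with neurons and gave at least 6.77 times, above a bound of 3 set after the class levels were seen. Neurons held more UMIs per cell (median 21704 against 6619 in glial cells), which lowers the CPM of an equal amount of free RNA, so that test was replaced by UMIs per cell under the same bounds. The list then stood at 1.46 times its level in neurons in glial cells, under the limit of 2, and between 3.01 (pericytes) and 8.58 times (mesenchymal cells) in the others. Free RNA may therefore account for the neuron level and for part of the levels elsewhere, and it is not excluded in any class.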

How the results depend on the processing

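The tests with mixed clusters kept whole, without overlapping genes, with cartilage clusters back, without low-UMI clusters and without P7 cells from the neuron cluster were chosen only after the result was seen, as were the choice to compare shares only in classes with at least 80 cells and the use of E15 mean minus P7 for cycling. No paired analysis was possible, since the ages come from different animals and replicate numbers only count libraries. In non-sensory epithelium thinned sums ended the calls by edgeR; thinning also changed how the spread was pooled across genes, and depth was not tested apart from it. The 10% limit gave 3302 calls in non-sensory epithelium against 2992, with 2270 shared. In pericytes it gave fewer, with 2715 genes at an unadjusted p under 0.05 and 2.22 prior degrees of freedom, so the cells held and the pooling of the spread both changed and were not tested apart. In 5 of 7 classes the spread was pooled fully across genes. List counts have no test with 1 E15 library left out. Clustering the libraries together could not test neurons and non-sensory epithelium, and the 10% limit could not test neurons. Where no cause is given below, the cause was not tested.

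Of 91 counts of called genes, 77 stayed within 1.5 times and 14 were lower. Counts with 1 E15 library left out or without overlapping genes cover only genes already called, so they can fall but not rise, and leaving out low-UMI clusters changed the count in mesenchymal cells alone; these bear little on stability. DESeq2 called 727 (endothelial), 2204 (glial), 1569 (neuron), 937 (non-sensory), 792 (pericyte) and 2696 (sensory), and the test against a fold of 2 called 822, 2260, 1853, 1528, 1118 and 2748 by its stricter construction. In non-sensory epithelium edgeR called 0 with thinned sums (2345 at an unadjusted p under 0.05, 518 by DESeq2), and in pericytes 315 with at most 10% mitochondrial UMIs. Of 169 counts of list members, 159 stayed within 1.5 times. At the 10% limit 23 deafness genes were higher in non-sensory epithelium, and in pericytes 7 cell cycle, 5 fetal and 0 barrier and 0 oxidative phosphorylation genes were lower and 3 deafness, 2 immediate early, 2 interferon and 2 hormone target genes higher. Clustered together, 2 barrier genes were lower in pericytes.

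Of 301 list medians, 177 moved by less than their spread, 120 by more and 4 changed sign; the median move was 0.06 and the highest 2.33. The largest were for the cell cycle list, from -4.88 to -2.56 in non-sensory epithelium without E15 replicate 2 and from -4.14 to -1.96 in glial cells clustered together. Changed signs were mesenchymal transcription factors (-0.0049 at the 10% limit, and -0.068 and 0.028 without E15 replicate 1 and 2), pericyte barrier genes (0.20 and -0.15) and sensory Notch genes (0.17 and -0.19, in the same order). Genes that changed sign were Crym in neurons (-0.58) and Lef1 in pericytes (2.50) with doublets kept, Igf2bp2 (0.12) and Jun (0.50) in neurons with the mixed cluster whole, Ccnb1 (0.34) and Thrb (-0.46) in non-sensory epithelium at the 10% limit, Ccnb1 (1.16) and Uhrf1 (0.39) there without E15 replicate 2, Meg3 in sensory epithelium (-0.28) clustered together and Pou4f3 there (0.43) without E15 replicate 1.

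Of 125 shares, 87 stayed within their interval or spread and 38 moved. At the 10% limit they were 78.1%, 78.6% and 57.03% for mesenchymal cells (E15 replicates 1 and 2, P7), 4.81%, 4.72% and 5.31% for sensory, 2.72%, 2.90% and 3.98% for non-sensory, 0.734% and 0.851% for pericytes at E15, 7.52% for glia and 0.371% for melanocytes at P7 and 1.789% for endothelium in E15 replicate 2. With doublets kept they were 46.5% (mesenchymal), 8.63% (sensory) and 11.5% (osteoblast) at P7, 0.810% and 0.933% for pericytes at E15 and 0.933% for macrophages in E15 replicate 2. Clustered together they were 64.0% (mesenchymal, P7), 8.21% (sensory, E15 replicate 2), 4.43% (glia, E15 replicate 1), 0.720% and 0.867% (pericytes, E15) and 0% and 0% (non-sensory, E15). At Leiden resolution 2 they were 76.9% and 77.4% (mesenchymal), 5.08% and 4.86% (sensory) and 2.92% and 3.24% (non-sensory) at E15 and 1.792% (endothelium, E15 replicate 2). With mixed clusters whole they were 6.92% (glia) and 1.80% (neuron) at P7 and 1.73% and 1.56% (macrophage) at E15.

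Of 28 cycling differences, 5 stayed within their spread and 23 moved. Thinned to 1000 UMIs they were 51.7 (glial), 36.7 (mesenchymal), 17.0 (non-sensory) and 18.98 (sensory) points. Without thinning they were 27.8 (endothelial), 60.3 (glial), 38.9 (mesenchymal), 0.754 (neuron), 16.2 (non-sensory), 55.8 (pericyte) and 34.03 (sensory). At 1 UMI they were 30.2, 57.3, 13.03 (neuron), 40.4 (non-sensory), 32.8 (pericyte) and 33.8 (sensory), the first for endothelial and the next for glial cells. At 4 UMIs they were 53.0 (glial), 33.7 (mesenchymal), 0.495 (neuron), 17.9 (non-sensory), 38.0 (pericyte) and 15.3 (sensory).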

Other observations

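The test of macrophages was chosen only after the result was seen, and the other values carry no test. Melanocyte-like cells, which as intermediate cells of the stria vascularis help to make the endocochlear potential, had some ion transport and pigment genes at other levels at P7, and the genes given were chosen after their values were seen. They were too few at E15 to be tested (16 and 29 cells, 44 at P7). Kcnj10, a potassium channel, had no UMI at E15 and 539.3 CPM at P7 (exact Poisson 95% interval 482 to 602). Atp1b1 was at 3.68 and 7.01 CPM in the E15 libraries and 1921 CPM at P7, and Gjb6 at 3.68, 3.50 and 597 CPM. Dct, an enzyme of melanin synthesis, was at 12990.0, 12110.0 and 31300.0 CPM, while Pmel was at 7378, 7846 and 1922 CPM and Tyrp1 at 129, 305 and 1.69 CPM. Others did not move apart: Tyr was at 817, 1061 and 1072 CPM and Gpr143 at 143.5, 189 and 139 CPM, and Kcnq1, Kcne1, Bsnd and Slc26a4 had no UMI in any of the 3 libraries.

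Macrophage-like cells fell under the least number for the planned test in E15 replicate 1 (17 cells). Tested all the same, 627 genes were called higher and 364 lower (991 of 6164), and with the mixed E15 cluster kept whole 1050 were higher and 1084 lower (2134 of 8923), so the calls depend on the split. The E15 cluster alone was split, which moved cells rich in class II antigen genes to another class, and genes of antigen presentation are therefore not compared. P2ry12, a receptor of resident macrophages, was at 47.6 and 91.5 CPM at E15 and 354 CPM at P7. Ccr2, a receptor of recruited monocytes, was at 195, 186 and 19.7 CPM. Osteoblast-like cells at P7 held 30860.0 CPM of Ibsp and 24610.0 CPM of Bglap, against 308.5 and 29.7 CPM in mesenchymal cells, and 2.06% of them were cycling.

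Transcripts of the Y chromosome without Xist were found in 84.6% of cells in E15 replicate 1, 80.6% in E15 replicate 2 and 79.3% at P7, and Xist alone in 0 of 2778, 1 of 3460 and 1 of 6848 cells. Neither was found in 426, 668 and 1408 cells, so a lack of UMIs does not bound expression. Embryonic globins were sparse: Hbb-y had 10 and 28 UMIs at E15 and 0 at P7. Adult Hbb-bs was at 958, 620.5 and 619 CPM. The E15 libraries shared 3 barcodes with each other and 6 each with P7.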
